A study of Mus musculus with 32 samples.

How the data were processed

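RNA was measured by sequencing in 32 mouse libraries: 8 from brachiocephalic arteries with lesions (4 KO and 4 WT animals) and 24 from cultured aortic smooth muscle cells (8 groups of 3). The deposited files hold raw counts per gene, 1 table for the lesions and 1 for the cultures, each with 23284 genes. Per the file headers, counts were made with featureCounts 1.4.4 on exons of a UCSC mm9 annotation, summed by gene name and without regard to strand. Lesion libraries were counted as fragments with both mates mapped, and culture libraries with each mate counted separately, so the culture counts are of reads. The authors' processing notes name CASAVA, STAR (without a version), featureCounts of Subread, DESeq2 and mm9. The share of even numbers among counts of 10 to 1000 was 50 to 50.9% in lesions and 53.8 to 60.3% in culture, which is the pattern that mates counted separately leave.

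Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), libraries were scaled by TMM, and dispersions and quasi-likelihood fits were robust. The 2 tables were fitted apart, with 14993 genes tested in lesions, 14496 in culture and 13380 in both. The 24 culture libraries were fitted in 1 model of 8 groups. There were 17 comparisons: KO against WT in lesions, 12 pairs of culture groups (4 for genotype, 4 for POVPC and 4 for hypoxia) and 4 interactions. A gene was called at an FDR (Benjamini-Hochberg, per comparison) under 0.05, on a 2-sided test, without a minimum fold. Standard errors were derived from the log2 fold change and its F statistic. Levels are mean CPM with SD over the libraries of a group. Where all libraries of a group had 0 counts, the fold is a bound against a floor of 3 counts over the group.

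Groups of genes were 24 lists written from general knowledge before the data were examined, as were the comparisons, their tests, the naming rule and most alternatives. They cover smooth muscle contractile, macrophage, T and B lymphocyte, thymocyte, endothelial, adventitial fibroblast, adipocyte, striated muscle, peripheral nerve and erythroid markers. They also cover extracellular matrix, matrix proteases and inhibitors, inflammatory cytokine and adhesion, interferon response, guidance and migration, hypoxia HIF target, NRF2 oxidative stress, unfolded protein and amino acid stress, heat shock, cholesterol synthesis, lipid efflux and storage, cell cycle, osteochondrogenic and pluripotency genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with an FDR over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. A list score is the mean of centred log2 CPM with a pseudocount of 0.5 CPM.

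Genes were named by a rule. Pou5f1 came first. For each comparison the 10 largest rises and 10 largest falls followed, among called genes with a mean of at least 1 CPM and libraries that did not overlap between the groups, which chance gives in 10% of genes with 3 libraries against 3. That last condition was dropped for interactions, and symbols of predicted or unnamed genes were left out. Up to 4 members of each list with the smallest p were added, whether or not they passed, and where nothing was called, the 5 genes with the smallest p. The text names a subset of these, some results are not reported here, and any gene outside the rule is named as chosen after its values were seen.

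The alternatives set before the data were examined were RLE factors, scaling by library size alone, DESeq2 1.42.0, no filter (at least 1 count), a stricter filter (5 CPM), the replicate number as a block, fits without robust estimation, a 2-fold minimum, each compared set of groups fitted alone, and each library left out in turn. Added after seeing the data were halved culture counts, the 3 shallowest culture libraries left out, and KO 4 and WT 1 both left out of the lesions. Genotype changes were compared between conditions by Spearman correlation, with a jackknife over libraries.

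The report gives the range of depth. The shallowest culture libraries were WT POVPC hypoxia 2 (8063121 counts), KO vehicle hypoxia 3 (11618385) and WT POVPC hypoxia 1 (13663755), in which 9.24, 8.07 and 5.80 multimapping alignments were listed per assigned one. Between replicates, counts varied at least 7.54 times as much as counting alone would give in lesions (chi-square per degree of freedom). The same measure was at least 6.51 in culture. There the mates counted separately make counting alone vary more, so this value overstates the excess and is not comparable with that of lesions. The steps were tested on simulated data with 200 changed genes. In the lesion design 7.58% of genes changed by 1.5-fold, 68.7% by 2-fold and 95.4% by 4-fold were called. The corresponding numbers were 56.1%, 86.2% and 98.5% for KO against WT under vehicle and normoxia, and 38.5%, 77.3% and 87.5% for the interaction of genotype and POVPC in normoxia. In these 3 designs 7, 6 and 7 unchanged genes were called. The simulated genes varied independently of one another, and no simulated library stood apart from its group. Real libraries did, so these shares test the steps and may overstate what the real data can detect, above all in lesions.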

Results

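Gene counts of 32 mouse libraries were compared between genotypes in 2 settings. The first was the brachiocephalic artery with its lesions, from C57BL/6 animals fed a Western diet for 18 weeks, with 4 Oct4 knockout (KO) and 4 wild-type (WT) animals. The second was a line of primary aortic smooth muscle cells per genotype, given vehicle or the oxidized phospholipid POVPC, in normoxia or in hypoxia (1% oxygen), with 3 libraries in each of the 8 groups. Changes are log2 fold changes with standard errors (±), levels are CPM (counts scaled to a common library size) with SD (±), and a gene rose or fell where edgeR gave a false discovery rate (FDR) under 0.05. Lists of genes were tested as groups with camera, with a Benjamini-Hochberg FDR across the lists of a comparison. Libraries held 6526099 (KO animal 1) to 11137414 counts (WT animal 2) in lesions and 8063121 (WT POVPC hypoxia 2) to 30231799 (KO POVPC normoxia 1) in culture.

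Pou5f1, which encodes Oct4, was at or near 0 in every library. Of the lesion libraries, WT animal 1 had 3 counts and the other 7 had 0. In culture 3 of 24 libraries had any: WT vehicle normoxia 1 had 1 count, KO POVPC normoxia 1 had 2 and KO vehicle hypoxia 3 had 1. A count of 3 would correspond to 0.269 to 0.46 CPM in lesions and 0.0992 to 0.372 CPM in culture, so the gene was at or under that floor in WT and KO alike. The counts therefore cannot check the genotype labels, and expression of the gene was not compared.

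As lists, macrophage genes were higher and contractile smooth muscle genes lower in lesions of KO animals than of WT animals (camera FDR 5.89e-24 and 6.82e-09, but adjusted p = 0.158 and 0.359 with an estimated correlation). All 20 macrophage genes were higher in KO, with a median of 0.89 (log2), among them the lipid receptor Trem2 (1.33 ± 0.27, 132 ± 47.8 CPM in KO against 52.5 ± 11.3 in WT), lysozyme Lyz2 (1.30 ± 0.28), the adaptor Tyrobp (1.02 ± 0.21) and the Fc receptor Fcgr3 (0.89 ± 0.19). All 18 contractile genes were lower, with a median of -0.43, among them Myocd (-0.72 ± 0.15), the coactivator that drives the contractile program, and Myh11 (-0.60 ± 0.16, 1836 ± 286 CPM in KO against 2783 ± 364 in WT), the smooth muscle myosin heavy chain. Genes for lipid uptake, storage and efflux were higher in 12 of 14 cases (median 0.50), such as the scavenger receptors Msr1 (1.11 ± 0.24) and Cd36 (0.54 ± 0.14) and the lipid droplet gene Plin2 (0.59 ± 0.14). The heme oxygenase gene Hmox1, a target of NRF2, was close to the threshold at 0.95 ± 0.11 (79.7 ± 8.82 against 41.4 ± 4.29 CPM, edgeR FDR 0.0575). Each lesion library was of artery tissue. A different share of cell types and a change within cells were therefore not told apart for any lesion list.

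No single gene passed the test in lesions: edgeR called 0 of 14993 genes, with 2216 under an unadjusted p of 0.05, and DESeq2 called 447 (305 higher and 142 lower in KO). The 5 genes with the smallest p that met the naming rule were Hmox1, the olfactory receptor Olfr111 (3.33 ± 0.39, FDR 0.0575), Dnahc8 (-1.95 ± 0.26, FDR 0.125), H2-M2 (2.10 ± 0.29, FDR 0.125) and Igsf9b (-0.81 ± 0.12, FDR 0.126). With adjustment over each list alone, 19 macrophage genes, 7 lipid genes and 9 endothelial genes were higher in KO and 7 contractile genes were lower.

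The lipid list passed camera at 1.6e-08, with adjusted p = 0.0801 with an estimated correlation. The macrophage, contractile and lipid calls held when any 1 animal was left out, as did those of 4 further lists. Endothelial genes were higher in 12 of 14 cases (median 0.34, FDR 1.02e-06, adjusted p = 0.359 with an estimated correlation), with Tek at 0.44 ± 0.096 and Tie1 at 0.50 ± 0.11. Matrix proteases and their inhibitors were higher in 13 of 18 (median 0.30, FDR 5.37e-06, adjusted p = 0.359 with an estimated correlation), with the stromelysin gene Mmp3 at 1.21 ± 0.20 and the macrophage elastase gene Mmp12 at 1.14 ± 0.30, and 7 of the 18 passed over the list alone. The median of this list was 0.14 without WT 4 and 0.20 without KO 4. NRF2 targets were higher in 13 of 16 (median 0.21, FDR 1.46e-05, adjusted p = 0.122 with an estimated correlation), with the peroxiredoxin gene Prdx1 at 0.68 ± 0.13 and the ferritin gene Ftl1 at 0.76 ± 0.20. Interferon response genes were lower in 14 of 16 (median -0.47, FDR 2.86e-05, adjusted p = 0.406 with an estimated correlation), with Usp18 at -0.56 ± 0.15 and Isg15 at -0.73 ± 0.24, and their median was -0.31 without WT 2.

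Calls on 11 other lesion lists were lost when some 1 animal was left out, and each was lost with an estimated correlation (lowest adjusted p = 0.512). Higher in KO was the cell cycle list (median 0.25, FDR 0.00742), at 0.11 without KO 4 (FDR 0.169) and 0.15 without WT 4 (0.0643). So were inflammatory cytokines and adhesion (0.24, FDR 0.00149), at 0.091 without WT 4 (0.0702) and 0.12 without KO 4 (0.0246), with the interleukin 1 antagonist Il1rn at 1.05 ± 0.24, and adventitial fibroblast genes (0.20, FDR 0.0042), at 0.15 without WT 1 (0.059). Adipocyte genes were higher too (0.24, FDR 0.0057), at 0.094 without KO 3 (0.0686), 0.17 without WT 2 (0.068) and 0.18 without WT 3 (0.056). Unfolded protein genes were higher at 0.065 (FDR 0.0481), at 0.038 without KO 4 (0.187) and 0.062 without WT 3 (0.101). For this list the median grew where WT 1 (0.099, FDR 0.0967), WT 4 (0.096, 0.0506), KO 1 (0.11, 0.0433) or KO 2 (0.13, 0.0398) was left out. Lower in KO was cholesterol synthesis (median -0.34, FDR 0.0154), at -0.10 without KO 4 (0.846), -0.12 without WT 4 (0.295) and -0.54 without KO 1 (0.000404). Heat shock genes (-0.17, FDR 0.0224) were at -0.15 without KO 4 (0.301), -0.050 without WT 4 (0.296) and -0.26 without KO 1 (0.0111). Osteochondrogenic genes (-0.57, FDR 0.0151) were at -0.47 without KO 1 (0.206), -0.60 without WT 2 (0.073), -0.27 without WT 3 (0.142) and -1.20 without KO 3 (5.61e-06). In this list Spp1, which macrophages also express, went the other way at 1.33 ± 0.34 (log2). Lower too were markers of tissue that can adhere to the artery. Thymocyte genes (-0.96, FDR 0.00559) were at -0.75 without KO 1 (0.14) and -0.56 without WT 1 (0.059). Striated muscle genes (-0.64, FDR 0.0154) were at -0.0040 without WT 3 (0.16), -0.45 without KO 1 (0.174), -0.47 without WT 4 (0.0702), -0.41 without WT 1 (0.0117) and -1 without WT 2 (0.000203). Peripheral nerve genes (-0.42, FDR 0.0151) were at -0.11 without KO 4 (0.449), -0.28 without WT 4 (0.0793) and -0.92 without KO 1 (0.000667).

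Lists with no call in lesions were T and B lymphocyte genes (median 0.10, FDR 0.807), extracellular matrix (-0.041, 0.867), guidance and migration (-0.11, 0.565), HIF targets (0.063, 0.883) and pluripotency genes (0.096, 0.883), and erythroid genes had too few measured members for a test (3, median -0.24). KO animal 4 and WT animal 1 stood apart from the rest on the first 2 principal components (83.2 on the first, against -38 to 8.04 in the others, and 39.9 on the second). Without these 2, a setting chosen after the results were seen, the macrophage median was 0.61, edgeR called 1 gene, and camera called the matrix list lower (median -0.34, FDR 0.00153) and HIF targets higher (0.13, 0.031). Without KO 4 alone the matrix list was called lower as well (-0.26, 0.0279).

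**Figure D1:**
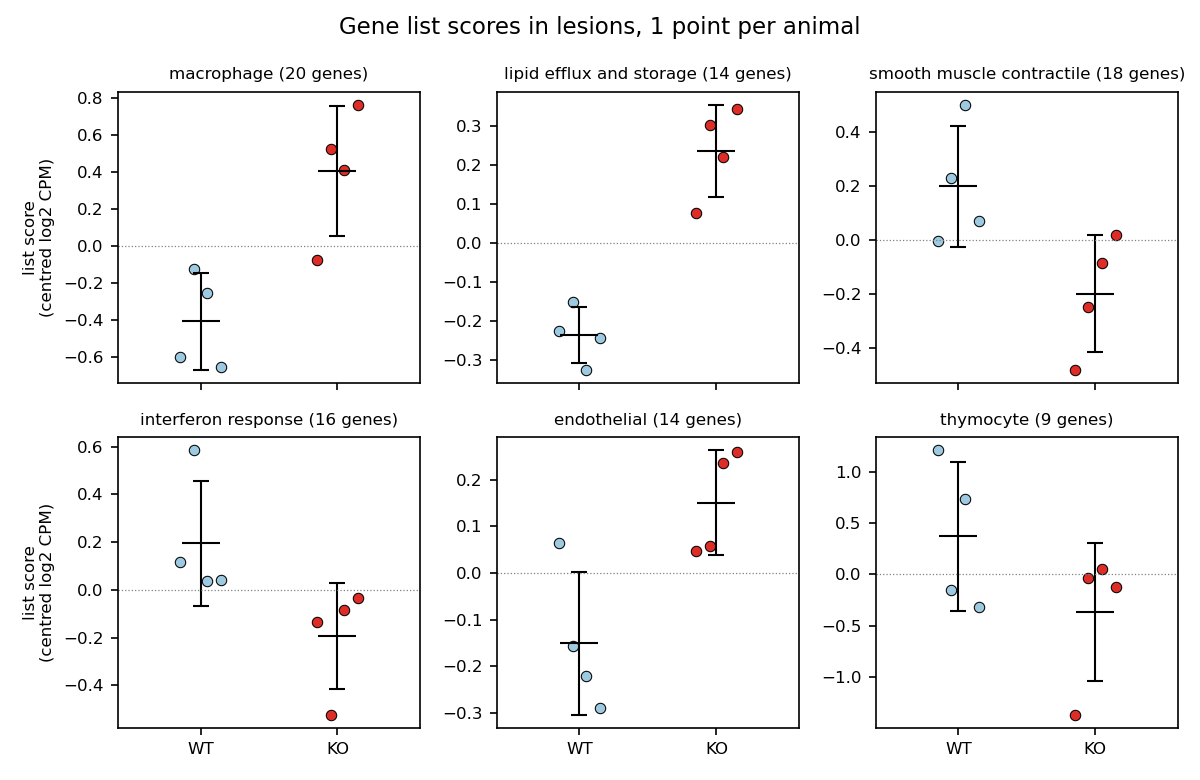
Scores of 6 gene lists in lesions, with 1 point per animal (4 WT in blue, 4 KO in red). A score is the mean over the genes of a list of the log2 CPM after each gene was centred across the 8 libraries. Bars show the mean and SD of the 4 animals. Macrophage and lipid scores were higher in all 4 KO animals than in all 4 WT animals, and the 2 groups overlapped in the contractile, endothelial and thymocyte scores.

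In cultured cells under vehicle and normoxia, 8778 of 14496 genes differed between the KO and the WT line by edgeR with 3 libraries a side (4313 higher and 4465 lower in KO), 3143 of them by at least 2-fold. The homeobox gene Nkx2-3 was at 40.1 ± 1.86 CPM in KO and had no counts in WT (at least 1160-fold higher), and Hoxb9, Hoxb7 and Hoxb8 were at least 387-fold, 260-fold and 253-fold higher. Calcrl, a receptor subunit for adrenomedullin, rose by 9.11 ± 0.21 to 206 ± 8.92 CPM. Thbd, which encodes thrombomodulin, fell by 9.28 ± 0.15 from 987 ± 18.1 to 1.58 ± 0.12 CPM, Mmp3 fell by 7.76 ± 0.22 from 2516 ± 119 to 11.7 ± 1.51 CPM, and Rorb was at least 385-fold lower. Scaled by library size alone, 37% of the calls were higher instead of 49.1%, with the median of all genes at -0.16 instead of -0.017. Each line came from 1 genotype, so genotype and line are confounded, and the p-values in culture measure the spread between triplicates of 1 line. The labels do not say whether these were wells, passages or days, so what that spread covers is unknown.

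Adventitial fibroblast genes rose in 8 of 12 cases and fell in 2 under vehicle and normoxia (median 1.34, camera FDR 4.95e-06), including the progenitor markers Pi16 (5.93 ± 0.13), Ly6a (4.90 ± 0.13) and Cd34 (6.32 ± 0.20). Inflammatory cytokine and adhesion genes fell in 9 of 16 and rose in 2 (median -1.46, FDR 0.00474), with the prostaglandin synthase Ptgs2 at -2.70 ± 0.12, the adhesion gene Vcam1 at -2.06 ± 0.075 and the chemokine Ccl7 at -4.46 ± 0.21. Contractile genes fell in 11 of 16 and rose in 2 (median -1.11, FDR 0.00607, adjusted p = 0.117 with an estimated correlation), with the kinase Mylk at -6.46 ± 0.30, Myh11 at -4.48 ± 0.46 and the actin regulator Lmod1 at -3.49 ± 0.18. Matrix proteases and inhibitors fell in 10 of 16 and rose in 6 (FDR 0.00397, adjusted p = 0.165 with an estimated correlation), led by the cathepsin Ctsk (-7.71 ± 0.19). NRF2 targets rose in 10 of 16 and fell in 3 (FDR 0.0189, adjusted p = 0.543 with an estimated correlation), with the cystine transporter Slc7a11 at 2.25 ± 0.10. Cell cycle genes rose in 13 of 18 and fell in 1 (FDR 0.02, adjusted p = 0.529 with an estimated correlation), with Kif11 at 1.25 ± 0.12. Of 4 pluripotency genes measured 3 rose, among them Myc (1.25 ± 0.14). The call of Klf2 (0.92 ± 0.30) was lost without WT vehicle normoxia 1 (FDR 0.0518) or KO vehicle normoxia 3 (0.0891).

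Under vehicle and hypoxia camera called 8 lists between the lines, and 0 with an estimated correlation. All 18 cell cycle genes were lower and 14 of them fell (median -1.24, camera FDR 0.000551, adjusted p = 0.248 with an estimated correlation), with the mitotic kinase Cdk1 at -3.30 ± 0.23. NRF2 targets fell in 12 of 16 (FDR 0.000551, adjusted p = 0.25 with an estimated correlation), with the glutathione synthesis gene Gclc at -1.99 ± 0.087. Unfolded protein genes fell in 13 of 15 (FDR 0.000551, adjusted p = 0.225 with an estimated correlation), with Xbp1 at -1.85 ± 0.087. Cholesterol synthesis genes fell in 15 of 17 (FDR 6.98e-05, adjusted p = 0.345 with an estimated correlation), with Nsdhl at -1.84 ± 0.12. HIF targets fell in 16 of 24 (FDR 0.00511, adjusted p = 0.26 with an estimated correlation), with the growth factor Vegfa at -1.69 ± 0.081. Inflammatory genes fell in 11 of 16 (FDR 0.00105, adjusted p = 0.0844 with an estimated correlation). Guidance genes fell in 13 of 21 (FDR 0.0109, adjusted p = 0.379 with an estimated correlation). Adventitial genes rose in 6 of 12 (FDR 0.00814, adjusted p = 0.113 with an estimated correlation). Among single genes, Thbs2 (8.29 ± 0.18) and Hoxb7 (at least 372-fold) were higher, and Thbd (-11.3 ± 0.18) and the growth factor binding gene Igfbp2 (-7.62 ± 0.29) were lower. edgeR called 8689 genes (4281 higher and 4408 lower, 3006 by at least 2-fold).

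With POVPC in normoxia, KO cells again had lower inflammatory genes and higher adventitial genes than WT cells. Inflammatory genes fell in 10 of 16 and rose in 2 (median -1.95, camera FDR 9.98e-06), with Ptgs2 at -4.54 ± 0.12 and Ccl7 at -6.36 ± 0.21. Adventitial genes rose in 8 of 12 and fell in 3 (median 1.64, FDR 7.79e-06), with Pi16 at 4.19 ± 0.11 and Dpt at 4.68 ± 0.17. Cell cycle genes fell in 13 of 18 (median -0.92, FDR 0.00526, adjusted p = 0.374 with an estimated correlation), with Top2a at -1.13 ± 0.098. Matrix proteases fell in 9 of 16 (FDR 0.00785, adjusted p = 0.374 with an estimated correlation), with Mmp3 at -8.68 ± 0.23. The scaffold gene Eps8l2 was at least 420-fold higher. edgeR called 8729 genes (4280 higher and 4449 lower, 3028 by at least 2-fold). With POVPC in hypoxia, inflammatory genes fell in 11 of 16 and rose in 1 (median -2.05, or -1.92 with genes absent from a group at their bound, FDR 0.00017), with the chemokine Ccl2 at -2.75 ± 0.17. Adventitial genes rose in 9 of 12 and fell in 2 (median 0.71, FDR 0.00141). NRF2 targets fell in 10 of 16 (FDR 0.0173, adjusted p = 0.621 with an estimated correlation), and the keratin gene Krt18 was at least 101-fold higher. Cholesterol synthesis genes fell in 13 of 17 (FDR 0.0117, adjusted p = 0.621 with an estimated correlation), a call lost without KO POVPC hypoxia 2 (FDR 0.0638). Here edgeR called 8351 genes (4356 higher and 3995 lower, 2726 by at least 2-fold).

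POVPC given to WT cells in normoxia went with higher cell cycle genes and NRF2 targets and lower contractile genes. The libraries differed in composition as well, without overlap: the ribosomal transcript Rn45s took 3.23, 9.36 and 11.1% of counts with POVPC and 1.31, 1.47 and 1.5% with vehicle, the RNA gene Rpph1 1.38 to 2.92% and 3.39 to 4.55%, and multimapping alignments per assigned one were 0.743 to 1.2 and 1.3 to 1.96. Effects of this difference were not separated from those of POVPC. All 18 cell cycle genes rose (median 1.37, camera FDR 7.08e-18), with Top2a at 1.54 ± 0.10 and the replication helicase Mcm2 at 1.23 ± 0.10. NRF2 targets rose in 12 of 16 (median 0.51, FDR 8.71e-10), with Slc7a11 at 2.92 ± 0.10 and Hmox1 at 1.46 ± 0.14. Cholesterol synthesis genes rose in 15 of 17 (median 0.90, FDR 4.11e-13, adjusted p = 0.0594 with an estimated correlation), with Fdps at 1.54 ± 0.14. Contractile genes fell in 11 of 16 and 1, Smtn, rose (median -1.16, FDR 1.59e-07), with the actin gene Acta2 at -2.13 ± 0.19 and the integrin gene Itga8 at -3.31 ± 0.20. Inflammatory genes rose in 9 of 16 and fell in 4 (median 1.00, FDR 0.000134), with Ptgs2 at 1.46 ± 0.10 and the complement gene C3 at 1.73 ± 0.14. Macrophage genes rose in 3 of 7 (median 0.98, or 0.71 with genes absent from a group at their bound, FDR 0.00306), with the galectin Lgals3 at 1.60 ± 0.11. Guidance genes fell in 12 of 21 (FDR 0.0081, adjusted p = 0.376 with an estimated correlation), with Sema3a at -1.10 ± 0.072. Unfolded protein genes fell in 6 of 15 and rose in 0 (median -0.26, FDR 0.0327, adjusted p = 0.376 with an estimated correlation), a call lost without WT POVPC normoxia 2 (0.0576). The largest rises included Ly6a (5.44 ± 0.14, 9.22 ± 0.47 to 400 ± 12.8 CPM) and the protease inhibitor Serpina3n (4.15 ± 0.12), and the matrix gene Thbs2 fell by 3.77 ± 0.14. edgeR called 3896 genes (1896 higher and 2000 lower, 1010 by at least 2-fold). Scaled by library size alone, 31.4% instead of 48.7% of the calls were higher, with the median of all genes at -0.13 instead of -0.019.

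In KO cells POVPC in normoxia changed few genes with all libraries kept. Col2a1 (-1.25 ± 0.19), the folate enzymes Aldh1l2 (-0.84 ± 0.11) and Mthfd2 (-0.45 ± 0.088), the asparagine synthetase Asns (-0.54 ± 0.093) and the ketone enzyme Oxct1 (-0.42 ± 0.076) fell. edgeR called 6 genes (1 higher and 5 lower), with 1075 genes under an unadjusted p of 0.05, and DESeq2 called 23. By library size alone 3 were called, 33.3% of them higher instead of 16.7%, and 0 where the compared groups were fitted alone (814 under an unadjusted p of 0.05). Mthfd2 lost its call without any 1 library other than KO vehicle normoxia 3 (FDR 0.0679 to 0.442), as did Oxct1 (0.0899 to 0.352) and Asns (0.0534 to 0.206). Mthfd2 also lost it with the replicate number as a block (0.0645), and both Mthfd2 (0.0655) and Oxct1 (0.0624) without robust estimation. Col2a1 lost it without KO vehicle normoxia 2 (0.0708) or KO POVPC normoxia 3 (0.0534). The inflammatory list was lower in 15 of 16 genes (median -0.28, camera FDR 0.00156, 0 of 16 called singly), and unfolded protein genes had 1 member that fell, Asns, and 6 over the list alone (FDR 0.000408, adjusted p = 0.254 with an estimated correlation). Cell cycle genes were lower in 14 of 18 (median -0.18, FDR 0.00156, adjusted p = 0.344 with an estimated correlation). Without KO vehicle normoxia 3 the number of genes was 310, and most were then higher with POVPC (224 higher and 86 lower). Under an unadjusted p of 0.05 there were 2867, and the inflammatory list had an FDR of 0.0623. Without KO vehicle normoxia 1 or 2 the number of genes called was 3 or 1, and without KO POVPC normoxia 1, 2 or 3 it was 2, 3 or 1.

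The difference between the lines in their response to POVPC in normoxia was itself tested, as the KO change minus the WT change. In KO the shares of Rn45s overlapped, with 1.71 to 3.94% of counts with POVPC and 1.29 to 8.02% with vehicle, but only through KO vehicle normoxia 3 (8.02%). The other 2 vehicle libraries were at 1.59 and 1.29%, so without that library the shift went as in WT. Rpph1 then did not overlap either (1.26 to 2.89% with POVPC, 6.91 and 4.23% with vehicle). Multimapping alignments per assigned one were 0.774 to 1.47 with POVPC and 3.88 and 2.84 in these 2. Effects of composition were not separated from this contrast either. Cell cycle genes had a negative difference in all 18 cases, 17 of them called (median -1.59, camera FDR 2.88e-21), with Top2a at -1.73 ± 0.14 (-0.18 ± 0.098 in KO). Contractile genes had a positive difference in 8 of 16 and a negative one in 1 (median 1.34, FDR 1.5e-07), with Acta2 at 1.82 ± 0.26 (-0.31 ± 0.19 in KO) and Itga8 at 3.54 ± 0.27 (0.23 ± 0.18 in KO). NRF2 targets were called with a negative difference in 10 of 16 (FDR 2.52e-08), with Slc7a11 at -2.97 ± 0.14 (-0.057 ± 0.093 in KO), and inflammatory genes in 7 of 16 (FDR 0.000139), with Ptgs2 at -1.84 ± 0.17. Cholesterol synthesis genes followed in 14 of 17 (FDR 5.92e-12, adjusted p = 0.0745 with an estimated correlation), with Fdps at -1.68 ± 0.19. Guidance genes were called with a positive difference in 10 of 21 (FDR 0.000186, adjusted p = 0.168 with an estimated correlation) and macrophage genes with a negative one in 2 of 7 (FDR 0.00102). The largest single differences included Ly6a (-5.37 ± 0.17, 0.066 ± 0.11 in KO) and Serpina3n (-4.54 ± 0.17). edgeR called 2344 genes (1184 positive and 1160 negative, 863 by at least 2-fold). Scaled by library size alone, 73.3% of the calls were positive instead of 50.5%, with the median of all genes at 0.20 instead of 0.025.

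**Figure D2:**
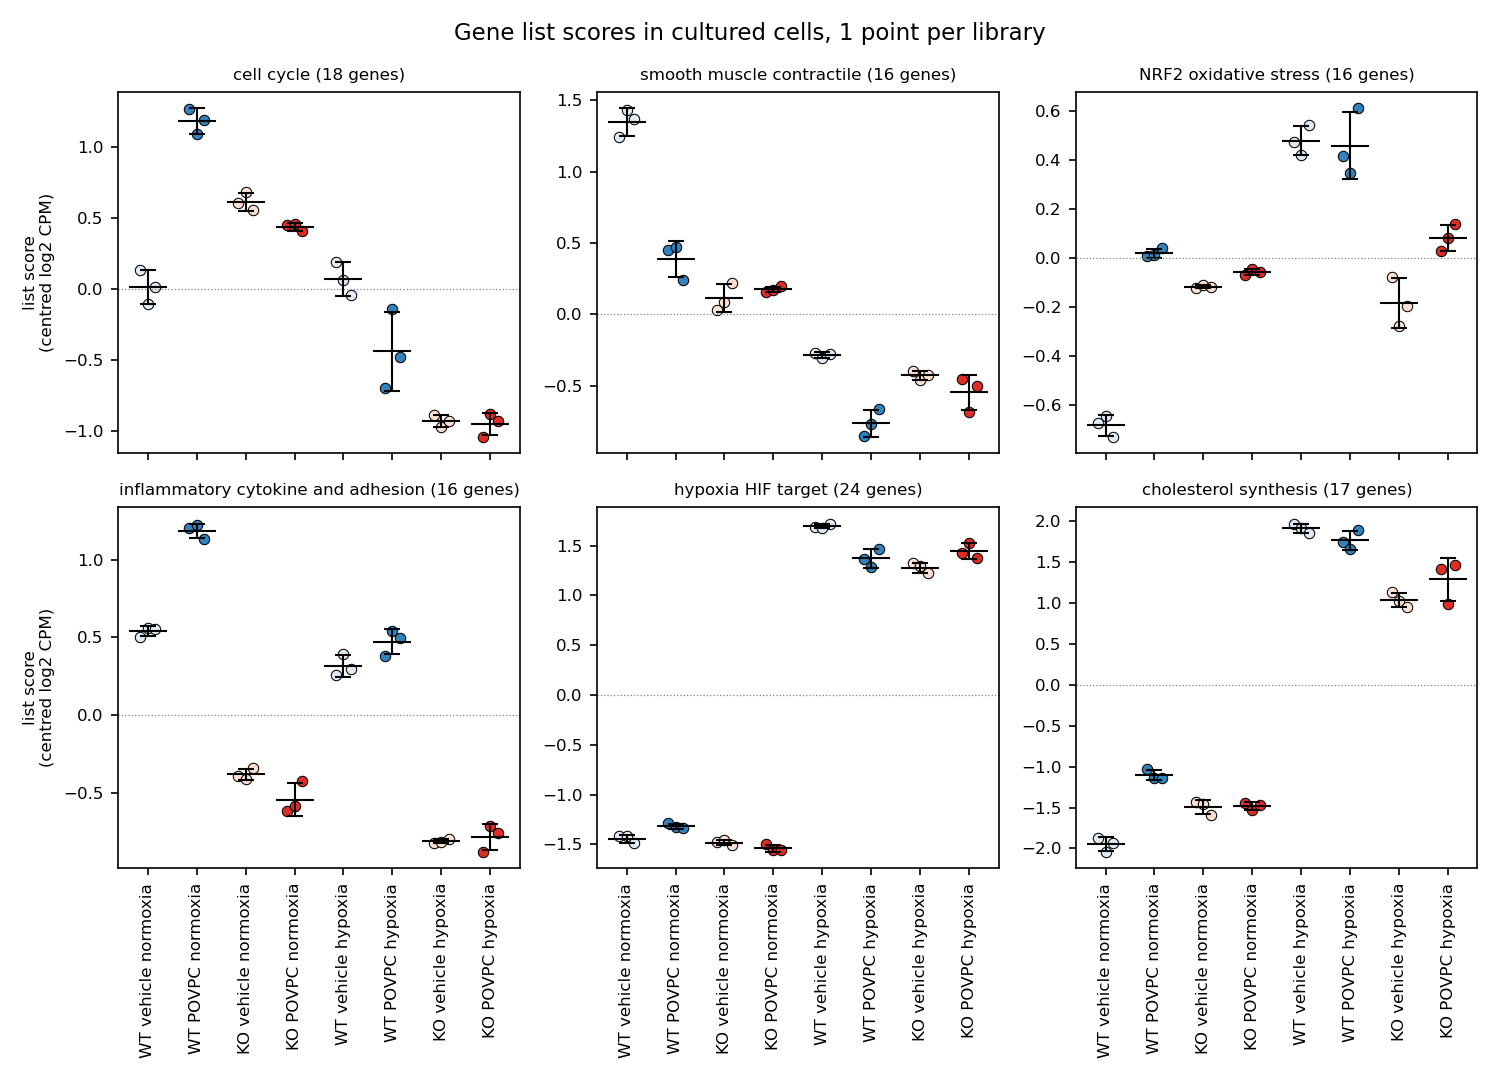
Scores of 6 gene lists in cultured cells, with 1 point per library and 3 libraries per group (WT in blue, KO in red, POVPC in the darker shade). A score is the mean over the genes of a list of the log2 CPM after each gene was centred across the 24 libraries. Bars show the mean and SD of the 3 libraries. Cell cycle scores were higher with POVPC than with vehicle in WT normoxia, and lower in WT hypoxia.

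For POVPC in WT cells under hypoxia camera called 12 of 19 lists, and 0 with an estimated correlation. Rn45s took 4.2 to 7.09% of counts with POVPC and 2.11 to 3.47% with vehicle. HIF targets fell in 11 of 24 (median -0.35, camera FDR 2.15e-05, adjusted p = 0.074 with an estimated correlation), with Vegfa at -1.04 ± 0.079. Cell cycle genes fell in 5 of 18 (median -0.65, FDR 2.15e-05, adjusted p = 0.074 with an estimated correlation), with Mcm5 at -1.08 ± 0.12. Heat shock genes rose in 3 of 11 (FDR 0.000619, adjusted p = 0.067 with an estimated correlation), with the inducible chaperones Hspa1a at 1.96 ± 0.25 and Hspb1 at 0.67 ± 0.14. Extracellular matrix genes fell in 12 of 20 and rose in 4 (FDR 0.00102, adjusted p = 0.243 with an estimated correlation), with Col8a1 at -1.53 ± 0.12 and Postn at -1.58 ± 0.20. Unfolded protein genes fell in 10 of 15 (FDR 0.00137, adjusted p = 0.111 with an estimated correlation). Contractile genes fell in 5 of 16 (FDR 0.00332, adjusted p = 0.074 with an estimated correlation), with Tagln at -3.28 ± 0.19. Lipid efflux and storage genes fell in 5 of 12 (FDR 0.0106, adjusted p = 0.074 with an estimated correlation), with the cholesterol exporter Abca1 at -1.47 ± 0.14. The transcription factor gene Tfcp2l1 rose by 2.46 ± 0.11. edgeR called 3037 genes (1191 higher and 1846 lower, 468 by at least 2-fold), 1720 where the 6 libraries were fitted alone and 1073 without the 3 shallowest culture libraries, which leaves WT POVPC hypoxia with 1.

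POVPC in KO cells under hypoxia raised heat shock genes, 5 of 11 of which rose while all 11 were higher (median 0.24, camera FDR 1.48e-09), with Hspb1 at 1.39 ± 0.16 and Hspa1b at 0.88 ± 0.11. NRF2 targets rose in 4 of 16 (FDR 4.67e-05, adjusted p = 0.158 with an estimated correlation), with Hmox1 at 1.02 ± 0.13, which was not called where the compared groups were fitted alone (1.01, FDR 0.0639). HIF targets rose in 4 of 24 (FDR 0.000892, adjusted p = 0.169 with an estimated correlation), with Ndrg1 at 0.75 ± 0.086. Cholesterol synthesis genes were higher in 17 of 17, with 1 called and 7 over the list alone (FDR 6.01e-05, adjusted p = 0.368 with an estimated correlation). Extracellular matrix genes fell in 3 of 20 (FDR 0.00717, adjusted p = 0.368 with an estimated correlation) and adventitial genes in 3 of 12 (FDR 0.0176, adjusted p = 0.158 with an estimated correlation), with Pdgfra at -0.76 ± 0.11. The factor Klf2 (1.88 ± 0.28) rose, and the chloride channel regulator Clca2 fell by 1.02 ± 0.11 from 636 ± 33.3 to 314 ± 57.4 CPM. edgeR called 588 genes (285 higher and 303 lower, 60 by at least 2-fold). DESeq2 called 991, and scaled by library size alone the count was 341 with 78.3% higher instead of 48.5%. It was 269 without KO vehicle hypoxia 2, 374 without KO vehicle hypoxia 3 and 300 without KO POVPC hypoxia 3.

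Tested as a difference, the POVPC response in hypoxia had a positive difference (KO minus WT) in 10 of 24 HIF targets (median 0.54, camera FDR 6.98e-10), with Vegfa at 1.15 ± 0.11 (0.11 ± 0.079 in KO) and Ero1l at 1.09 ± 0.11. Unfolded protein genes were called in 8 of 15 (FDR 1.8e-05, adjusted p = 0.127 with an estimated correlation), cholesterol synthesis genes in 5 of 17 (FDR 0.000249, adjusted p = 0.364 with an estimated correlation) and cell cycle genes in 4 of 18 (FDR 0.00224, adjusted p = 0.218 with an estimated correlation), all positive. Tfcp2l1 had a difference of -2.58 ± 0.15 (-0.12 ± 0.10 in KO), and Tagln one of 2.45 ± 0.25. In KO the Rn45s shares overlapped between POVPC (3.75 to 8.31%) and vehicle (2.95 to 4.06%), unlike in WT. Multimapping alignments per assigned one were 0.988 to 2.75 with POVPC and 1.89 to 8.07 with vehicle in KO. In WT they were 1.56 to 9.24 with POVPC and 0.952 to 3.14 with vehicle. Effects of composition were not separated from this difference. edgeR called 1358 genes (854 positive and 504 negative, 296 by at least 2-fold), 828 with the 4 groups fitted alone and 426 without the 3 shallowest culture libraries. By library size alone 80.6% of the calls were positive instead of 62.9%, with the median of all genes at 0.13 instead of 0.033, and DESeq2 gave 51.7%.

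Hypoxia raised HIF targets in both lines and lowered adventitial fibroblast genes. In WT vehicle Rn45s took 2.11 to 3.47% of counts in hypoxia and 1.31 to 1.5% in normoxia. HIF targets rose in 23 of 24 in WT vehicle (median 3.67, camera FDR 6.25e-26), with the glycolytic genes Pgk1 at 4.86 ± 0.087 and Ldha at 4.47 ± 0.10 and the mitophagy gene Bnip3 at 4.96 ± 0.12. Cholesterol synthesis genes rose in 16 of 17 (median 4.15, FDR 2.45e-21), with the sterol demethylase Cyp51 at 4.15 ± 0.11. Adventitial genes fell in 9 of 12 and rose in 2 (FDR 0.00151), with the growth factor receptor Pdgfra at -5.34 ± 0.12, the proteoglycan Dcn at -3.04 ± 0.095 and Lum at least 814-fold lower. Contractile genes fell in 12 of 16 (FDR 0.000514), with Itga8 at -7.07 ± 0.29. Extracellular matrix genes fell in 16 of 20 (FDR 1.69e-08, adjusted p = 0.0528 with an estimated correlation), with Postn at -4.92 ± 0.15. NRF2 targets rose in 13 of 16 (FDR 4.33e-06, adjusted p = 0.0556 with an estimated correlation), with Slc7a11 at 4.46 ± 0.11. Unfolded protein genes rose in 10 of 15 (FDR 4.35e-05, adjusted p = 0.0556 with an estimated correlation), with Trib3 at 4.52 ± 0.12. Heat shock genes rose in 8 of 11 (FDR 0.00307). The kininogen gene Kng1 was at least 755-fold higher. edgeR called 9866 genes in WT vehicle (4748 higher and 5118 lower, 4169 by at least 2-fold). By library size alone 36.4% of the calls were higher instead of 48.1%, with the median of all genes at -0.21 instead of -0.032.

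In WT cells with POVPC, camera also called the cell cycle list lower in hypoxia, where multimapping alignments per assigned one were 1.56 to 9.24 against 0.743 to 1.2 in normoxia. Of the 18 cell cycle genes 17 fell and Pcna rose (median -2.40, camera FDR 1.66e-05, adjusted p = 0.0767 with an estimated correlation), with Top2a at -3.26 ± 0.11. HIF targets rose in 23 of 24 (median 2.90, FDR 3.06e-26) and cholesterol synthesis genes in 16 of 17 (median 3.01, FDR 4.27e-19), with Pgk1 at 4.07 ± 0.084. Adventitial genes fell in 11 of 12 (FDR 9.57e-07), with Dcn at -4.13 ± 0.10. Heat shock genes rose in 9 of 11 (FDR 8.33e-05), with Hsp90aa1 at 1.66 ± 0.068. Extracellular matrix genes fell in 18 of 20 (FDR 4.35e-10, adjusted p = 0.0531 with an estimated correlation). Contractile genes fell in 11 of 16 (FDR 0.00362, adjusted p = 0.0558 with an estimated correlation) and inflammatory genes in 10 of 16 (FDR 0.0316, adjusted p = 0.0819 with an estimated correlation). The growth factor associated gene Wisp2 fell by 7.14 ± 0.20 and the scavenger receptor Scara5 fell by 6.99 ± 0.15. edgeR called 9586 genes (4612 higher and 4974 lower, 3966 by at least 2-fold), with the median of all genes at -0.11 by library size alone instead of -0.024.

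In KO cells hypoxia raised HIF targets as well. With vehicle, HIF targets rose in 22 of 24 (median 3.07, camera FDR 6.37e-26), with the glucose transporter Slc2a1 at 4.39 ± 0.097. Adventitial genes fell in 11 of 12 (median -2.51, FDR 4.02e-13), with Lum at -7.20 ± 0.19. Cholesterol synthesis genes rose in 16 of 17 (median 2.69, FDR 4.43e-17, adjusted p = 0.0631 with an estimated correlation). Extracellular matrix genes fell in 17 of 20 (FDR 3.22e-09, adjusted p = 0.0801 with an estimated correlation), with the collagen Col8a1 at -5.21 ± 0.12. Cell cycle genes fell in 14 of 18 (FDR 0.000331, adjusted p = 0.147 with an estimated correlation), with Cdk1 at -3.73 ± 0.23. The cornified envelope gene Sprr1a rose by 6.67 ± 0.42 from 4.59 ± 2.23 to 477 ± 46.9 CPM and Ankrd37 by 6.25 ± 0.18. With POVPC, HIF targets rose in 23 of 24 (median 3.14, FDR 7.99e-26) and cholesterol synthesis genes in 17 of 17 (median 2.93, FDR 4.79e-17), with Slc2a1 at 4.88 ± 0.099 and Cyp51 at 2.93 ± 0.10. Adventitial genes fell in 11 of 12 (FDR 1.38e-12). Extracellular matrix genes fell in 18 of 20 (FDR 2.67e-10). Heat shock genes rose in 10 of 11 (FDR 0.000504). The guidance receptor Nrp2 fell by 4.77 ± 0.15 and Pi15 fell by 7.47 ± 0.19. edgeR called 9481 genes with vehicle (4729 higher and 4752 lower, 3787 by at least 2-fold) and 9924 with POVPC (5003 and 4921, 4250 by at least 2-fold).

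The response to hypoxia differed between the lines under vehicle, tested as the KO change minus the WT change. In KO the Rn45s shares overlapped between hypoxia (2.95 to 4.06%) and normoxia (1.29 to 8.02%), unlike in WT. This overlap rests on KO vehicle normoxia 3 alone (8.02%). The other 2 normoxia libraries, at 1.59 and 1.29%, were below those in hypoxia, as in WT. NRF2 targets were called with a negative difference in 15 of 16 (median -1.23, camera FDR 7.7e-13), with Slc7a11 rising by 4.46 ± 0.11 in WT and 0.97 ± 0.093 in KO (-3.48 ± 0.14) and Gclc rising in WT (0.94 ± 0.084) and falling in KO (-1.35 ± 0.085, difference -2.29 ± 0.12). Cell cycle genes were called in 16 of 18, all negative (median -1.98, FDR 6.58e-12), with Top2a at -0.85 ± 0.10 in WT and -3.44 ± 0.12 in KO (-2.60 ± 0.16). Cholesterol synthesis genes had a negative difference in 16 of 17 (FDR 7.7e-13, adjusted p = 0.0886 with an estimated correlation), with Stard4 at -1.84 ± 0.15. HIF targets had one in 14 of 24 (FDR 0.0104, adjusted p = 0.26 with an estimated correlation), with Vegfa at -1.36 ± 0.11. Contractile genes had a positive difference in 8 of 16 and a negative one in 2 (FDR 0.00712, adjusted p = 0.0901 with an estimated correlation), with Cald1 at 2.05 ± 0.16 and Acta2 at 2.47 ± 0.27. Adventitial genes had a negative one in 8 of 12 (FDR 0.00875, adjusted p = 0.0886 with an estimated correlation), with Ly6a at -4.96 ± 0.17. The cytokine receptor Il13ra1 rose in WT (1.95 ± 0.19) and fell in KO (-4.21 ± 0.23, difference -6.16 ± 0.30). edgeR called 5670 genes (2788 positive and 2882 negative, 2076 by at least 2-fold), and by library size alone 60.1% of the calls were positive instead of 49.2%, with the median of all genes at 0.13 instead of 0.028.

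Within WT cells the response to POVPC differed between hypoxia and normoxia. The composition of the libraries shifted in opposite directions as well. Multimapping alignments per assigned one were lower with POVPC in normoxia (0.743 to 1.2, against 1.3 to 1.96 with vehicle). In hypoxia they were mostly higher with POVPC (1.56 to 9.24, against 0.952 to 3.14). Effects of these shifts were not separated from the reversals given here. Cell cycle genes were called with a negative difference (hypoxia minus normoxia) in 17 of 18 (median -2.05, camera FDR 4.93e-21), with Top2a rising by 1.54 ± 0.10 in normoxia and falling in hypoxia (-0.87 ± 0.12, difference -2.41 ± 0.15). Cholesterol synthesis genes had a negative difference in 16 of 17 (FDR 5.56e-13, adjusted p = 0.0718 with an estimated correlation). NRF2 targets had one in 13 of 16 (FDR 4.37e-08, adjusted p = 0.0548 with an estimated correlation), with Slc7a11 at -2.20 ± 0.13. HIF targets had one in 12 of 24 (FDR 0.000272, adjusted p = 0.0937 with an estimated correlation), with Ldha at -1.38 ± 0.12. Ly6a rose by 5.44 ± 0.14 in normoxia and fell in hypoxia (-0.65 ± 0.12, difference -6.09 ± 0.17). Without the 3 shallowest culture libraries the fall was not called (-0.28, FDR 0.121). Foxs1 did the reverse (-2.23 ± 0.19 and 1.32 ± 0.23, difference 3.55 ± 0.30). edgeR called 3413 genes (1466 positive and 1947 negative, 1086 by at least 2-fold), and 1993 without the 3 shallowest culture libraries. By library size alone 57.8% of the calls were positive instead of 43%.

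The genotype contrasts were compared with one another across genes. Between vehicle and POVPC in normoxia, 3297 genes were higher in KO in both, where 1273 would be expected if the 2 sets were independent, and 3306 were lower in both (1370 expected), with a Spearman correlation of 0.765 across 14496 genes (jackknife SE over libraries 0.021). In hypoxia the corresponding numbers were 3356 (1286), 3264 (1215) and 0.778 (SE 0.052), and between vehicle normoxia and vehicle hypoxia 2566 (1274), 2629 (1358) and 0.525 (SE 0.021), with 867 genes called in opposite directions. The contrasts share no library but all compare the same 2 lines. Genotype differences in lesions had little relation to those in culture across the 13380 genes tested in both, with correlations of 0.143 (SE 0.052) for vehicle normoxia, -0.034 (SE 0.044) for vehicle hypoxia, 0.028 (SE 0.045) for POVPC normoxia and -0.051 (SE 0.043) for POVPC hypoxia. Mmp3, for example, was 7.76 ± 0.22 lower on the log2 scale in KO cells under vehicle and normoxia, while its value in lesions was 1.21 ± 0.20.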

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

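In lesions 6 of 56 measures had 1 animal apart from the other 3 of its group, where chance alone sets apart about 1 in 20. The splits of libraries given below were tested after the results were seen.

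The thymocyte score of KO animal 1 was -1.37, against -0.119 to 0.0503 in the other 3 KO animals. The peripheral nerve score of WT animal 4 was 0.606, against 0.153 to 0.223 in the other WT animals. The interferon response score of WT animal 2 was 0.584, against 0.0349 to 0.116. WT animal 1 stood apart in 3 measures of the library: 1.54 alignments outside genes per assigned one (0.96 to 1.06 in the others), 1.04 multimapping alignments per assigned one (0.841 to 0.867) and 2.96% of counts on the ribosomal transcript Rn45s (1.41 to 1.62%). The lower interferon list in KO lesions rests partly on WT animal 2, but its call held without that animal or any other. With an estimated correlation the call was lost, as camera then called 0 of 23 lesion lists.

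Each of the 4 interactions, which test whether 2 groups respond differently, called genes. The POVPC response differed between the lines in 2344 genes in normoxia and in 1358 in hypoxia, the hypoxia response differed between the lines in 5670 under vehicle, and the POVPC response of WT cells differed between oxygen levels in 3413. Of 40 regroupings of the libraries each, 4 gave as many genes in the first (highest other 2749), 2 in the second (2420), 7 in the third (7478) and 2 in the fourth (3637), the real one included, so chance cannot be excluded by these shares. The regroupings with large counts kept at least 1 pair of groups whole or exchanged, so they carry a real contrast of another kind. Of those that mixed both pairs (26, 32, 29 and 32), 0 gave as many genes, and the highest counts were 0, 1, 0 and 0. Mixing puts libraries of different conditions into 1 group, which widens its spread and averages out the contrast. Low counts follow from that alone, so they do not decide about chance.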

How the results depend on the processing

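The halved counts, the 3 shallow culture libraries left out, and KO 4 and WT 1 both left out were chosen after the results were seen. The other alternatives were set in advance.

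In lesions, where edgeR called 0 genes (2216 at an unadjusted p under 0.05), no filter gave 11, DESeq2 447, and leaving out KO 4 and WT 1 gave 1. With any 1 animal left out the number was 0.

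A 2-fold minimum lowered the KO against WT numbers in culture to 3143 (vehicle normoxia), 3006 (vehicle hypoxia), 3028 (POVPC normoxia) and 2726 (POVPC hypoxia). For POVPC it gave 1010 (WT normoxia), 468 (WT hypoxia), 1 (KO normoxia) and 60 (KO hypoxia), and for hypoxia 4169 (WT vehicle), 3966 (WT POVPC), 3787 (KO vehicle) and 4250 (KO POVPC). For the interactions it gave 863 and 296 (genotype by POVPC in normoxia and hypoxia), 2076 (genotype by hypoxia) and 1086 (POVPC by hypoxia in WT).

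Fitted with the compared groups alone, POVPC in WT hypoxia gave 1720 genes, POVPC in KO normoxia 0 and genotype by POVPC in hypoxia 828. Without the 3 shallow libraries the numbers were 1073 for POVPC in WT hypoxia, 426 for genotype by POVPC in hypoxia and 1993 for POVPC by hypoxia in WT. That setting leaves WT POVPC hypoxia with 1 library, which is assumed to vary like the other groups. POVPC in KO normoxia gave 3 genes by library size alone, 3 without robust estimation and 23 with DESeq2, and 1 to 310 with 1 library left out. POVPC in KO hypoxia gave 341 by library size alone, 991 with DESeq2, and 269 to 532 with 1 library left out.

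Of 327 tests of lists, camera called 139, and 38 with an estimated correlation. With fry 206 were called, 117 of them also by camera in the same direction, and with RLE factors 138, of which 137 were shared. With 1 library left out, 25 of 144 lesion tests and 48 of 900 culture tests of called lists lost their call. For the 215 named values of single genes, alternatives gave the same verdict 3525 times, lost a call 35 times and gained one 34 times, with 0 reversals.

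Among genes with at least 5 CPM, the genotype correlations in culture were 0.594 (vehicle normoxia and vehicle hypoxia), 0.819 (vehicle normoxia and POVPC normoxia), 0.567 (vehicle normoxia and POVPC hypoxia), 0.702 (vehicle hypoxia and POVPC normoxia), 0.845 (vehicle hypoxia and POVPC hypoxia) and 0.682 (POVPC normoxia and POVPC hypoxia). With 1 library left out, they ranged from 0.743 to 0.766 (vehicle normoxia and POVPC normoxia), 0.612 to 0.625 (vehicle hypoxia and POVPC normoxia), 0.724 to 0.793 (vehicle hypoxia and POVPC hypoxia) and 0.578 to 0.609 (POVPC normoxia and POVPC hypoxia, the lowest without WT POVPC hypoxia 3). The correlation of lesions with POVPC normoxia ranged from -0.00565 to 0.0428.

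Replicate numbers did not pair the libraries. The median residual correlation of libraries with the same number was -0.0973 over 4 lesion pairs and 0.0165 over 84 culture pairs, and with the number as a block edgeR called 0 lesion genes (1600 at an unadjusted p under 0.05).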

Other observations

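The guidance, matrix and lipid lists had no call between the KO and the WT line under vehicle and normoxia, and their single genes went both ways. The guidance ligand gene Slit3 fell by 5.59 ± 0.20 on the log2 scale and its receptor Robo1 fell by 4.40 ± 0.17, Sema3c fell by 2.39 ± 0.076, and Sema3d rose by 3.37 ± 0.13. In lesions Slit3 was at -0.44 ± 0.10, without passing. Of 21 guidance genes 5 rose and 12 fell in the KO line (camera FDR 0.151). Elastin Eln fell by 4.78 ± 0.22 and its crosslinking enzyme Lox fell by 1.56 ± 0.097, while the collagen gene Col8a1 rose by 1.78 ± 0.10 and the matrix list was not called (7 rose and 9 fell of 20, camera FDR 0.953). The lipid droplet gene Plin2 rose by 1.39 ± 0.083, the liver X receptor gene Nr1h3 fell by 3.33 ± 0.29, and Apoe, which carries cholesterol out of cells, fell by 1.48 ± 0.17.

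All regroupings of libraries, the tests of Pou5f1 neighbours other than the one with the thymocyte score, the Hox trend with paralog number, and the number of POVPC calls without KO vehicle normoxia 3 were chosen after the results were seen. In lesions all 35 splits of the 8 animals gave at least the 0 genes of the real split (highest other 3), as any split must, so that count says nothing about chance. At an unadjusted p under 0.05, 2 of 35 gave as many as the real 2216 (highest other 2455). For each of the 12 pairs of culture groups, 3 against 3 allow 10 splits, too few for a share under 0.05, and 1, the real one, gave as many genes. The real numbers were those given above (6 to 9924), and the highest other was 2 for KO against WT with POVPC in hypoxia and for POVPC in WT hypoxia, and 0 in the rest. For POVPC in KO normoxia a split gave 2428 genes at an unadjusted p under 0.05 and another 2050, against 1075 for the real one. This points to a structure among these 6 libraries. Both splits set KO vehicle normoxia 1 and 2 against KO vehicle normoxia 3, which was grouped with POVPC libraries.

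Lesion genes with small p gathered near Pou5f1. Within 5 Mb of it lie 12 of the 100 genes with the smallest p. Among them are Glo1, Ddr1 and H2-T23, named after their values were seen. By comparison, 132 other runs of 180 tested genes held a median of 1, a 95th percentile of 3 and at most 5. Neighbouring runs on a chromosome shared genes, so the 132 runs are not independent. A strain haplotype carried with the targeted allele is a candidate explanation that stays open: of the 12 genes 8 were tested in culture, 4 went the same way there, Ddr1 was called that way, and Glo1 and Gm8801 were called the opposite way (lesion -0.96 and -4.33, culture 1.31 and 2.23). With the thymocyte score in the model 9 of the 100 lay there (highest other run 6). As far as the score measures it, this argues against RNA of thymus in some lesions as the whole cause. Among KO animals the score mainly sets apart KO 1 (-1.37, against -0.119 to 0.0503), so the adjustment may be incomplete. Without the H2 and Olfr families 4 remained in the window, above the 95th percentile of 3 (median 1) and under the highest of 5 in the other runs. The requirement to exceed every other run was set after these values were seen. Reads shared between paralogs therefore cannot be told apart from a haplotype. Other causes, among them a different share of cell types in KO lesions, were not tested.

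Most Hox genes tested were higher in the KO line. Of 25 tested, 15 rose in all 4 genotype contrasts, among them Hoxb5, Hoxa7 and Hoxc9, and Hoxb4 fell in all 4, with the same numbers (15 and 1) by library size alone and with RLE factors. Hoxc13, chosen after its values were seen and of the highest number, was lower (0.477 ± 0.143 CPM in WT and 0 in KO under vehicle and normoxia, FDR 0.000344), and Hoxd8, chosen likewise, was higher in normoxia but at -0.80 and -1.38 in hypoxia, without passing. The mean change correlated with the paralog number (rho 0.437), but lines from different positions along the body axis stay a hypothesis that may not hold, since this trend was found in the same values. An effect of Oct4 loss wherever it occurs cannot be told apart, since genotype and line are the same contrast in culture and 2 of the 15 were tested in lesions. These were Hoxc4 (-0.87 ± 0.60) and Hoxa5 (0.18 ± 0.16). Their median was -0.348, with an SE of 0.368 from resampling the 2 genes, which does not measure spread between animals.

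KO cells had few POVPC calls in normoxia. Over the 3896 genes called in WT, the KO change had a slope of -0.0119 on the WT change (leave-one-library-out SE 0.0148), far under the 0.5 set in advance, which argues against a response of WT size hidden by spread. Without KO vehicle normoxia 3 the slope was -0.00329, which argues against that library hiding a response of WT size. The library did lower the number of calls, which was 310 without it instead of 6, with 72.3% of them higher instead of 16.7%. It also had 0.793 multimapping alignments per assigned one (3.88 and 2.84 in the other 2 vehicle libraries) and 8.02% of counts on Rn45s (1.59 and 1.29%). A difference in library quality thus stays open beside a culture that was not vehicle. The library was close to KO POVPC normoxia 1 in multimapping (0.774). On the fourth principal component the 2 were at -10.1 and -9.01, and the other vehicle libraries at 15.2 and 11.2. Without KO vehicle normoxia 3, multimapping did not overlap between vehicle and POVPC (0.774 to 1.47). Library composition may therefore contribute to the 310 calls, which was not tested. A lost response to POVPC through Oct4 and a difference between the lines both stay open, untested. The WT change used for the slope came from libraries that also differed in composition without overlap, as given in the Results. That change may therefore not be POVPC alone.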
